A study of Mus musculus with 6 samples.

How the data were processed

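RNA was measured in 6 libraries of electroporated mouse cortex at E15.5, 3 with the Ccnd2 Thr280Ala edit and 3 with GFP only, grouped by their labels. Per the labels' protocols, polyadenylated RNA was extracted with an RNeasy kit. The submitters' processing notes name cutadapt, featureCounts, DESeq2 and the build mm10, without versions. The aligner, the annotation, the strand setting of the counting and the depth of each library are not given in the sources used here. Reads of overlapping and antisense genes can therefore be shared, and this is stated beside Dlx6, Sox1ot and Ccnd2.

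The single table used here is the authors' own comparison, with no columns of values per sample (0 such columns). Per the file headers it gives, for each gene, the base mean, a signal that is the mean over the libraries of counts divided by size factors. The deposited log2 fold change and its standard error are on the log2 scale, without a stated numerator. The deposited Wald statistic is a score, the fold change over its standard error, which the values obey to within 2.0e-14. The deposited p-value and adjusted p-value come from the authors' DESeq2 run. The adjusted values equal a Benjamini-Hochberg adjustment over the 18446 genes with a p to within 4.3e-14, so no filter on low means was applied in it, and 0 genes with a mean above 0 lack a p. Rn45s, a ribosomal RNA precursor, holds 1.59% of the sum of base means.

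A gene was called when the authors' adjusted p was under 0.05. No model was refitted, since counts per sample were not used here. The rule for named genes was Ccnd2, the 10 largest folds per direction among called genes with a mean of at least 50 (8 positive and 7 negative genes qualified), and up to 4 members per list, called members with the smallest p first and then those with the smallest p. Gene models with only a number were counted and not named, and called members of a list could all be named where they were 6 or fewer. Some genes that the rule takes in are counted but not reported here by name. The gene lists (29, of which 28 had measured members), tests, named-gene rule and first alternatives were fixed before the data were examined. Decoding of reads, 5 further gene lists and a set test with a correlation of 0.2 were added afterwards. Medians and signs of the further lists were taken over members with a mean of at least 10, and values over all members are given where members were left out.

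Each list was tested in 3 ways. Fisher's exact test compared called with uncalled genes. limma 3.58.1 in R 4.3.3 ran cameraPR on the Wald statistic, which asks whether a list lies apart from other genes, with a preset correlation of 0.01 between genes. The median log2 fold change was set among 10000 random lists matched on mean expression in 20 bins. All were adjusted over the lists by Benjamini-Hochberg. Random lists treat the genes of a list as independent. A correlation for whole lists could not be estimated without values per sample, so the highest preset correlation that kept a call, up to 0.90, was found: 0.90 for meninges and fibroblasts, 0.72 for ventral progenitors, 0.17 for G1/S, 0.14 for the hem, 0.13 for Wnt targets, 0.12 for intermediate progenitors, 0.11 for G2/M and microglia, 0.04 for D-type cyclins, immediate early and ribosomal protein genes, and 0.03 for endothelial cells. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

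Whole reads of low genes were recovered from the base means. The 739 genes with the lowest means take 6 values, each the worth of a single read in 1 library, and the sign of their fold change puts 3 libraries on each side. They give size factors of 1.11, 1.02 and 0.904 on the positive side and 1.11, 1.04 and 0.850 on the negative side, so relative depth differed little, while total reads stay unknown. For each of 111 genes with a mean of up to 75, taken from the called genes and the lists, sets of 6 whole numbers were searched that give the deposited mean within a relative tolerance of 6e-15. Exactly 1 set was found for 110 of them, and for the other one the deposited fold change picked 1 of the sets found. The fold change was not used for the 110, and the ratio of side means from the reads had its sign in 102 of 103 genes with reads on both sides, with a median difference of 0.0095 log2 units. Simulated reads were recovered for 200 of 200 genes with 0 wrong, and when the real means were shifted at random 8 of 111 had any solution. The search was first run up to a mean of 42 with a tolerance of 1e-14, and the limit was raised after those reads had been seen so as to take in Dlx6, Aldh1a2 and Foxd1. Libraries are numbered within a side by falling size factor, and no library is matched to a label. Where a side had 0 reads for a gene, list medians were recomputed with that gene at a floor of 3 reads over the side, and no median moved. For lists with at least 3 resolved members, the mean correlation between members within sides was estimated from log2(normalised reads + 1) on 4 residual degrees of freedom, with negative estimates set to 0, and cameraPR was rerun with it. Lists without an estimate stayed at 0.01 in that adjustment, so each list was also tested with all lists at its own estimate. It was 0.98 for meninges and fibroblasts, 0.93 for Wnt targets, 0.75 for ventral progenitors, 0.55 for the hem, 0.15 for immediate early and -0.082 for ribosomal protein genes among the lists past the set test, and the resolved members are the low genes of each list.

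Coordinates and the coding sequence of Ccnd2 come from GENCODE M21 on GRCm38, the mm10 assembly, whose names match 24366 of the 25239 symbols. Permutation tests across genes used 100000 resamples. Like the sign, binomial and Fisher's exact tests, they treat genes as independent and do not measure the spread between libraries. The steps were tested on simulated data with the deposited standard errors for all 18446 genes of this comparison, with 100 genes changed per size: 90% of log2 changes of 1 and 99% of those of 2 were called, 6.44% of calls were unchanged genes, and 3 of 3 shifted lists and 0 unshifted lists were found. Genes were simulated as independent, so false calls of lists with correlated members were not tested. All changed genes had a mean of at least 50, so recovery of changes below that mean was not tested either. Wald statistics were drawn with the deposited standard errors taken as correct, without simulated reads or libraries. These shares therefore do not measure false calls that arise when libraries of a side differ. Alternatives covered the threshold, a fold minimum, other sets of genes for the adjustment, other correlations, ranks and random lists.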

Results

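Polyadenylated RNA was sequenced from the electroporated part of the embryonic mouse cortex. C57BL/6J embryos were electroporated in utero at E13.5, and the tissue was taken at E15.5. The labels give 6 libraries in 2 groups of 3. One group received a CRISPR edit that introduces the Thr280Ala variant of Ccnd2, which encodes cyclin D2, a D-type cyclin that binds CDK4 and CDK6 in G1. The other group received GFP only. The labels list no group edited without the variant, so effects of the variant and of the editing itself cannot be told apart. The labels do not say whether the libraries of a group came from separate embryos, so the p-values measure only the spread between these libraries. Standard errors of the Y-linked genes ran from 2.16 (Eif2s3y) to 2.78 (Uty), against a median of 0.12 over genes with a mean of at least 50. Libraries within at least 1 side therefore differed in sex-linked reads, which argues against technical repeats of 1 sample there. Whether a library was 1 embryo or a pool stays open. The data used here are 1 comparison of the groups made by the authors, with 25239 gene symbols, of which 18446 have a fold change and 6793 are listed with a mean of 0. Which group is the numerator of the fold change is not stated in the sources used here. Values above 0 are therefore called the positive side and values below 0 the negative side, and neither side is assigned to the variant or to GFP.

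The comparison asks which transcripts differ between cortex electroporated for the Ccnd2 edit and cortex with GFP only. No value used here measures the share of edited cells in a library, so differences confined to edited cells could be missed. The authors' deposited table gave 25 genes an adjusted p under 0.05, of which 16 lay on the positive side and 9 on the negative side. Genes of the meninges, the fibroblast layers that cover the brain, lay on the positive side, led by the collagen gene Col1a1. Genes of the ventral forebrain, led by the homeobox genes Dlx5 and Dlx6, lay on the negative side. Ccnd2 itself did not pass the test. The split of 16 to 9, 64% positive, did not differ from an even split by an exact binomial test (two-sided p = 0.23). Of the genes called, 8 on the positive side and 1 on the negative side had a mean under 50 normalised counts. Over the 12019 genes with a mean of at least 50 the median log2 fold change was -0.0089, with quartiles of -0.071 and 0.061. At an unadjusted p under 0.05 the authors' deposited table holds 730 genes, 3.96% of those tested, where 5% would be 922.3 genes.

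Ccnd2 was among the most abundant transcripts, with a mean of 20340 normalised counts in the authors' deposited table. Its log2 fold change there was 0.41 with a standard error of 0.29 and an adjusted p of 1.00 by DESeq2, so no difference was detected. The 95% interval of the log2 fold change was -0.17 to 0.98, which spans 0. The standard error of Ccnd2 was wide for its abundance: 1 of the 200 genes nearest in mean had a wider one, and their median was 0.075. Among the 932 genes with a mean of at least 5000, Ccnd2 ranked 2 by absolute fold change and 5 by standard error. Ccnd2 lies on the minus strand of chromosome 6, from 127125162 to 127152193 in mm10 (GENCODE M21, gene ENSMUSG00000000184.12). Codon 280 is ACC, threonine, in the coding part of exon 5 of 5 of the annotated transcript used here, at 127130365 to 127130367. The surrounding coding sequence in the reference is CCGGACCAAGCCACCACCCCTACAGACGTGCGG, which reads PDQATTPTDVR from residue 275 of a protein of 289 residues. A fold change of the whole gene does not tell edited from unedited transcripts. The antisense genes Gm43126 and 9330179D12Rik overlap Ccnd2, and the strand setting of the counting is not given in the sources used here.

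Taken as a list with their kinases, the D-type cyclins lay on the positive side. All 5 measured members had positive fold changes with a median log2 of 0.095, and the list passed the set test (limma cameraPR, adjusted p = 0.030). The list includes the edited gene Ccnd2, whose log2 fold change of 0.41 was its largest. Ccnd3 had a log2 fold change of 0.25 ± 0.11 (standard error) in the authors' deposited table, Ccnd1 0.10 ± 0.17 and Cdk6 0.09 ± 0.13. No member was called over all genes, nor when adjusted over the list alone (0 genes). With a preset correlation of 0.05 between genes in place of 0.01 the call was lost, at an adjusted p of 0.052.

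**Figure D1:**
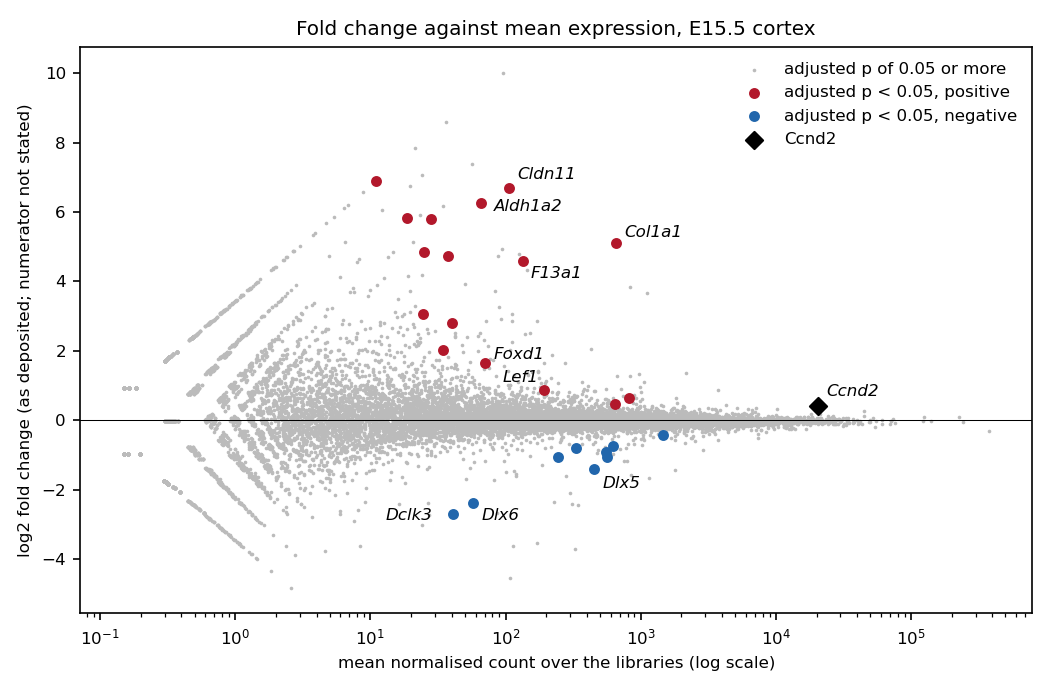
Log2 fold change (vertical axis, as deposited, numerator not stated) against the mean normalised count (horizontal log axis) for the 18446 genes tested. Coloured points are the 25 genes with an adjusted p under 0.05, 16 positive and 9 negative, and the black diamond is Ccnd2 at a mean of 20340 and a log2 fold change of 0.41.

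Meningeal genes gave the widest difference among the lists. All 10 members of the meninges and fibroblasts list had positive fold changes, with a median log2 of 3.88 (cameraPR adjusted p = 5.9e-31), and 3 members were called over all genes against 9 adjusted over the list alone (Fisher's exact test, adjusted p = 7.3e-06). Col1a1, a chain of type I collagen, had a log2 fold change of 5.11 ± 1.16 in the authors' deposited table, with an adjusted p of 0.024. Aldh1a2, the retinoic acid synthesising enzyme of the meninges, stood at 6.26 ± 1.56 and the transcription factor gene Foxd1 at 1.65 ± 0.41 in the authors' deposited table, each with an adjusted p of 0.047. Foxc1, a transcription factor gene needed for meningeal development, had 1.09 ± 0.29 in the authors' deposited table and missed the threshold with an adjusted p of 0.071.

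The other calls on the positive side included genes known from the arachnoid, from macrophages and from connective tissue. Cldn11, a tight junction gene expressed in the arachnoid layer, had the largest fold among called genes with a mean of at least 50, a log2 of 6.70 ± 1.52 in the authors' deposited table (adjusted p = 0.024). F13a1, which encodes a coagulation factor subunit made by tissue macrophages, had 4.59 ± 1.05 (adjusted p = 0.024) in the authors' deposited table. Smaller folds there were those of Bgn, which encodes a matrix proteoglycan, at 0.65 ± 0.15 (adjusted p = 0.024), and Rcn3, which encodes a calcium-binding protein of the secretory pathway, at 0.46 ± 0.11 (adjusted p = 0.036). The 8 positive genes with a mean under 50 were Cp, Slc13a4, Ccr1, Msx1, Gja5, Col13a1, Alx4 and Lrrc17, named outside the fixed rule after their values were seen.

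The reads behind the low genes differed between libraries of 1 side. Base means of low genes can be resolved into whole reads per library, numbered within each side by falling size factor and not matched to the labels, and 14 meningeal genes (5 of the fixed list and 9 of a list added later) were resolved. Their summed normalised reads were 1159 and 1641 in libraries 1 and 2 of the positive side, but 157 in library 3, against 165, 143 and 175 in the libraries of the negative side. Library 3 was the lowest of its side for 14 of the 14 genes. Aldh1a2 had 179, 233 and 2 reads on the positive side and 1, 2 and 2 on the negative side, and Foxd1 had 137, 152 and 45 against 40, 33 and 30. Among the 10 called positive genes that were resolved, library 3 was again the lowest of its side for all 10. The summed meningeal reads were 6.11 times as high on the positive side, and 3 of the 10 splits of the 6 libraries gave a ratio as large (exact permutation p = 0.30, where 3 against 3 cannot go below 0.10). The set test kept its call with a correlation estimated from the 5 resolved members of the fixed list (adjusted p = 5.3e-04 with an estimated correlation, and 0.0021 with all lists at that correlation). That rerun used the same Wald statistics per gene and did not compare libraries. It therefore does not outweigh the split of the libraries.

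**Figure D2:**
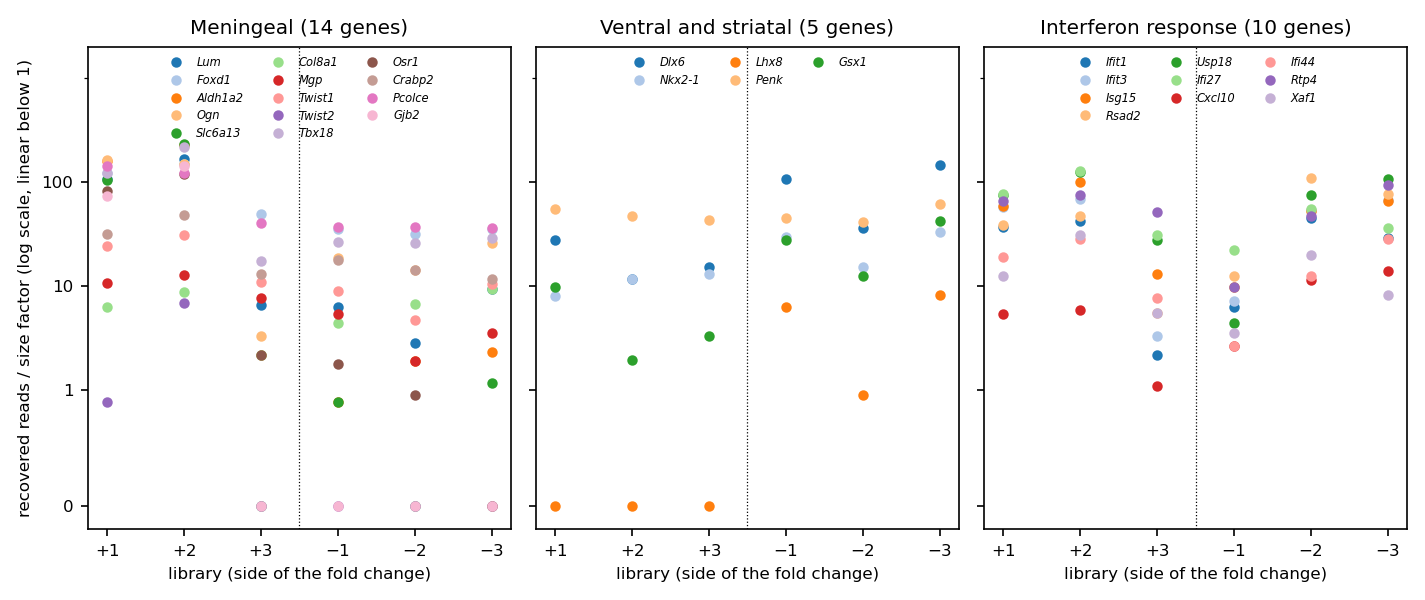
Whole reads divided by the size factor (vertical axis, log scale and linear below 1) for each of the 6 libraries, 3 per side of the fold change, with 1 coloured point per gene. The summed meningeal reads were 1159, 1641 and 157 on the positive side and 165, 143 and 175 on the negative side, the ventral and striatal sums 101, 72.4 and 75.2 against 217, 107 and 292, and the interferon sums 450, 654 and 149 against 81.8, 486 and 531.

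Ventral forebrain genes lay on the negative side. In the list of ventral progenitors and interneurons 14 of 16 members had negative fold changes, with a median log2 of -1.17 (cameraPR adjusted p = 1.1e-19), and 2 members were called over all genes against 10 adjusted over the list alone (Fisher's exact test, adjusted p = 0.0029). Dlx5 had a log2 fold change of -1.40 ± 0.28 (adjusted p = 0.0068) and Dlx6 of -2.38 ± 0.53 (adjusted p = 0.024) in the authors' deposited table. Both are homeobox genes of GABAergic neurons and their progenitors. Sp9 at -1.66 ± 0.52 missed the threshold in the authors' deposited table, with an adjusted p of 0.22. Dlx6 is uncertain as a single gene, since the antisense Dlx6os1 overlaps it and had -1.57 ± 0.56 in the authors' deposited table.

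The remaining calls on the negative side included other homeobox genes and Dclk3, which had the largest negative fold of all calls. The homeobox genes Meis1 and Pbx3, which encode partner proteins with known expression in the ganglionic eminences and striatum, had log2 fold changes of -1.06 ± 0.24 and -0.91 ± 0.20 in the authors' deposited table, each with an adjusted p of 0.024. Sox1ot stood at -1.05 ± 0.24 (adjusted p = 0.024) in the authors' deposited table and overlaps Sox1 on the same strand, so reads of the pair may be divided between them. Sox1 had -0.40 ± 0.12 in the authors' deposited table with an adjusted p of 0.23. Fam222a had -0.78 ± 0.20 with an adjusted p of 0.047 in the authors' deposited table. Dclk3, a kinase gene with a mean under 50, was named after its value was seen, at -2.70 ± 0.64 in the authors' deposited table, and 1 gene model with only a number was counted and not named.

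Reads per library were uneven here too. Over 5 resolved genes of the ventral and striatal lists the summed normalised reads were 217, 107 and 292 in libraries 1 to 3 of the negative side and 101, 72.4 and 75.2 on the positive side. Library 2 was the lowest of the negative side for 5 of the 5 genes. The sums were 2.47 times as high on the negative side, and no other of the 10 splits gave a ratio as large (exact permutation p = 0.10, the smallest that 3 against 3 allows). With a correlation estimated from 3 resolved members, the call of the fixed list depended on the adjustment: adjusted p = 0.016 with an estimated correlation for it and the other resolved lists, and adjusted p = 0.057 with all lists at its estimate. Dlx6 had 120, 38 and 124 reads on the negative side against 31, 12 and 14, and Dclk3 had 91, 17 and 96 against 14, 10 and 9.

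**Figure D3:**
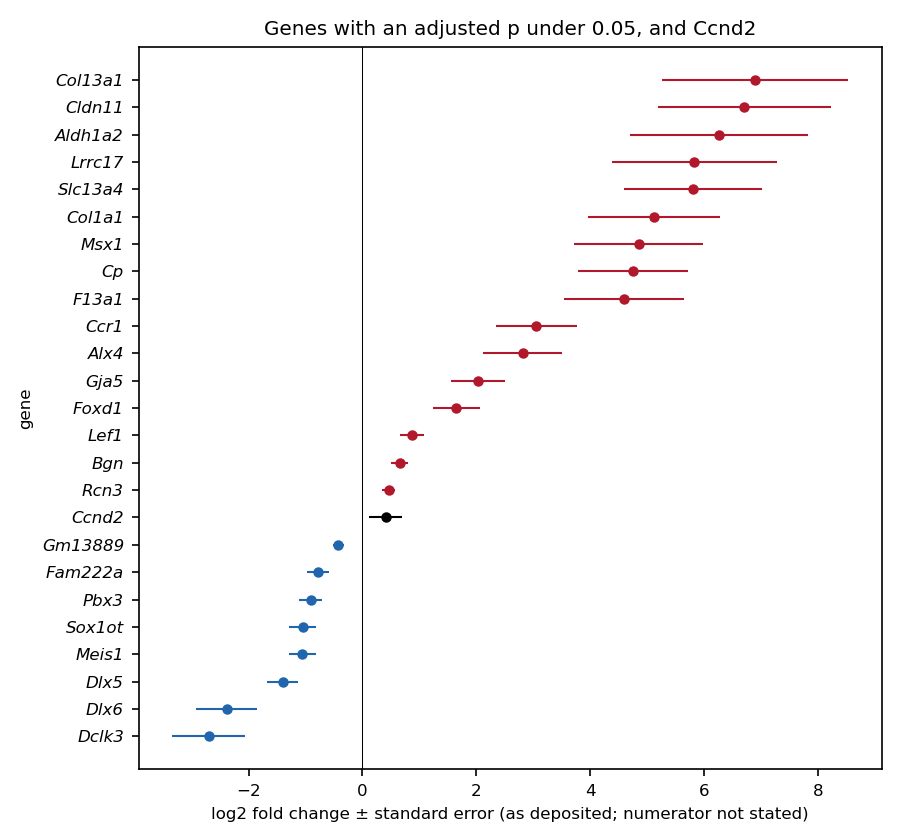
Log2 fold change with its standard error (horizontal axis, as deposited, numerator not stated) for 24 of the 25 genes with an adjusted p under 0.05 and for Ccnd2 (vertical axis). The median standard error over all 25 was 1.01 for the positive calls and 0.24 for the negative calls.

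Cell cycle genes shifted by small amounts to the negative side. In the G1/S and DNA replication list 23 of 24 members had negative fold changes, with a median log2 of -0.13 (cameraPR adjusted p = 1.8e-07), and in the G2/M and mitosis list all 22 did, with a median of -0.095 (adjusted p = 2.1e-04). No member of either list was called, and 0 were called adjusted over the list alone. E2f2, a transcription factor gene of S-phase entry, had -0.55 ± 0.20 in the authors' deposited table, the nucleotide reductase subunit gene Rrm2 -0.33 ± 0.13 and the replication licensing gene Cdc6 -0.31 ± 0.13. The proliferation marker Mki67 had -0.28 ± 0.14 and the topoisomerase gene Top2a -0.26 ± 0.13 in the authors' deposited table. Both lists kept their call up to preset correlations of 0.17 and 0.11. Striatal genes moved to the same side, with a median log2 of -2.34 over 13 genes of a list added later. The CDK inhibitors and pocket proteins did not pass the set test (adjusted p = 0.84), with Cdkn1c at 0.33 ± 0.13 and Rbl1 at -0.37 ± 0.15 in the authors' deposited table.

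Intermediate progenitors, the dividing precursors that give rise to most cortical neurons, lay on the positive side. In that list 9 of 11 members had positive fold changes, with a median log2 of 0.16 (cameraPR adjusted p = 9.9e-04), and no member was called. Pallium-restricted genes, a list added later that shares 8 of its 13 genes with the fixed lists, were positive in 12 of 13 with a median of 0.28. Its 9 members outside the intermediate progenitor list had a median of 0.095 with 8 positive, while the striatal genes had a median of -2.34. Eomes had 0.34 ± 0.16 in the authors' deposited table, Neurog2 0.35 ± 0.16 and Neurod4 0.47 ± 0.26. Radial glia did not pass the set test (adjusted p = 0.38), although Sox2 at -0.33 ± 0.10 in the authors' deposited table was past the threshold adjusted over the list alone (adjusted p = 0.016). Neither pan-neuronal (adjusted p = 0.098), deep-layer (0.073) nor upper-layer genes (0.051) passed the set test. Against random lists matched on expression, radial glia lay on the positive side (adjusted p = 0.014), and pan-neuronal (0.022) and upper-layer genes (7.0e-04) on the negative side. Their median log2 fold changes were 0.047, -0.074 and -0.16. Random lists ignore standard errors and treat members as independent, so these p-values alone do not show a difference between the sides. Foxp2 at -0.83 ± 0.24 and Inhba at -0.84 ± 0.27 in the authors' deposited table were each the only member of the deep-layer and upper-layer lists past the threshold adjusted over the list alone.

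Genes of the cortical hem and Cajal-Retzius cells lay on the positive side in 10 of 11 members, with a median log2 of 0.32 (cameraPR adjusted p = 2.9e-04), a call lost with an estimated correlation (adjusted p = 0.19 with an estimated correlation). Wnt2b had 1.38 ± 0.60 in the authors' deposited table. Wnt8b, a gene of the hem and medial wall, had 59 reads in library 1 of the positive side and 0 in each of the others, and Wnt3a had 13 reads in that library and 0 elsewhere. The Wnt targets passed as well, with 7 of 11 positive and a median of 0.21 (adjusted p = 5.6e-04), and lost the call on ranks (adjusted p = 0.051) and with the correlation of their resolved members (adjusted p = 0.36 with an estimated correlation). Lef1, a transcription factor gene of Wnt signalling, was its only called member, with 0.87 ± 0.21 and an adjusted p of 0.029 in the authors' deposited table. Summed over 4 resolved Wnt targets, normalised reads were 90.4, 63.6 and 3.32 on the positive side and 25.2, 9.60 and 22.4 on the negative side.

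Among non-neural cells, microglial genes had a median log2 fold change of 0.49 with 10 of 12 positive (cameraPR adjusted p = 0.0011), and endothelial genes 0.20 with 7 of 10 positive (adjusted p = 0.026), a call lost with a correlation of 0.05 (adjusted p = 0.061) and on ranks (0.11). The complement gene C1qa had 0.86 ± 0.51 and the endothelial cadherin gene Cdh5 0.35 ± 0.16 in the authors' deposited table. No gene of either list was called. Pericytes (adjusted p = 0.34), choroid plexus (0.098) and erythroid cells (0.53) did not pass, the last with 6 members measured and 4 listed with a mean of 0. Aqp1 at 2.21 ± 0.80 in the authors' deposited table was the only choroid plexus gene past the threshold adjusted over the list alone. Glial precursors (adjusted p = 0.11) and diencephalon (0.37) did not pass either. Aldh1l1, an astrocyte marker, had -0.67 ± 0.18 and Lhx9, a thalamic gene, 1.68 ± 0.52 in the authors' deposited table, each past the threshold only when adjusted over its list alone.

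Of the remaining lists, immediate early genes passed with a median log2 of 0.18 and 9 of 12 positive (cameraPR adjusted p = 0.013), and ribosomal protein genes with 0.040 and 68 of 83 positive (adjusted p = 4.4e-04). Both calls were lost with a correlation of 0.05, at adjusted p-values of 0.052 and 0.052, and that of the immediate early genes also against random lists (0.055) and with the correlation of their resolved members (adjusted p = 0.15 with an estimated correlation). Ier2 had 0.35 ± 0.13 and Rplp0 0.11 ± 0.06 in the authors' deposited table. The PI3K-AKT-mTOR pathway had a median of -0.012 (adjusted p = 0.85), with Akt2 at 0.12 ± 0.08 and Mtor at -0.11 ± 0.10 in the authors' deposited table. Notch (0.84), p53 (0.84), interferon (0.53), hypoxia (0.84) and sex-linked genes (0.62) did not pass the set test, and 0 of 13 mitochondrially encoded genes are in the table. Against random lists interferon genes lay on the positive side (adjusted p = 0.029) and sex-linked genes on the negative side (0.0073). That test ignores standard errors and treats members as independent. Resolved interferon genes had an estimated correlation of 0.87, and the Y-linked genes had standard errors of 2.16 to 2.78. Neither p therefore shows a difference between the sides. Of the sex-linked genes, Xist had -0.31 ± 0.55 and Ddx3y -0.56 ± 2.39 in the authors' deposited table. Median, mean and test differed in sign for 8 lists, none past the threshold: PI3K-AKT-mTOR, deep-layer, Notch, p53, hypoxia, diencephalon, glial precursors and erythroid cells.

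**Figure D4:**
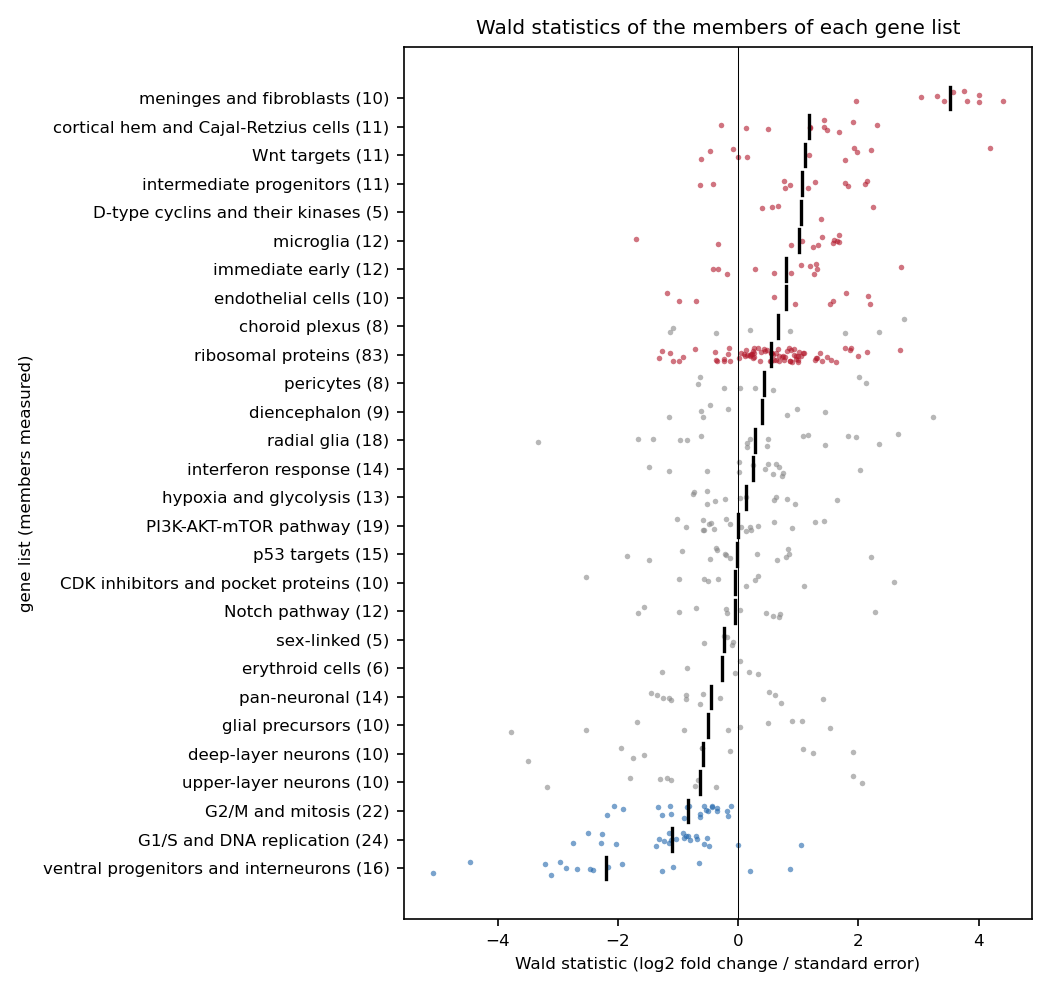
Wald statistic (horizontal axis, log2 fold change over its standard error, numerator not stated) of each member of the 28 measured gene lists (vertical axis, members measured in brackets), with the mean of each list as a black bar. Red and blue lists are the 9 positive and 3 negative lists past the set test, and the meningeal and ventral lists lie farthest from 0.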

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

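Among the settings in this part, the set tests with a correlation of 0.2 or an estimated one and all tests on resolved reads were chosen after the data were seen. From 25 genes, the count moved to 2 at an adjusted p under 0.01, to 52 (37 positive, 15 negative) under 0.1, and to 16 (8 and 8) when the adjustment ran over means of at least 50, where fewer genes are tested and the 9 called genes below that mean cannot be called. It was 18 with an absolute log2 fold change of at least 1, 25 over all genes with a p and 31 over means of at least 10. The positive share of 64% became 71.2% (exact binomial p = 0.0032) under 0.1, a looser threshold that admits more genes. The binomial test counts genes as independent. Yet library 3 was the lowest of the positive side for all 10 resolved positive genes called under 0.05. The small p therefore does not establish an imbalance between the sides. Ccnd2 stayed uncalled under both adjustments tried. Of 12 lists, 8 passed with a correlation of 0.05, 10 on ranks, 12 over means of at least 50, and 16 against random lists, of which 11 were among the 12. With a correlation of 0.2 only 2 remained, the meningeal and ventral lists, and the ventral list lost its call above 0.72. A correlation could be estimated for 6 of the 12 lists, for reruns on the same Wald statistics per gene and not across libraries. The meningeal list kept its call with the estimated correlation, while the hem, Wnt target and immediate early lists did not. The ventral list kept its call (adjusted p = 0.016) unless all lists were set to its estimate (0.057). For the ribosomal list this was no test. Its negative estimate (-0.082, from 6 low genes) was set to 0, below the preset 0.01, so its p could only fall. Lists past the threshold kept their direction in every setting run, but among lists past it in neither, the CDK inhibitors, PI3K-AKT-mTOR and p53 lists turned from negative to positive over means of at least 50 (adjusted p = 0.96 each). Against random lists PI3K-AKT-mTOR turned to positive (0.84) and diencephalon to negative (0.11), and the cause was not tested. No paired analysis was possible because the table has no values per sample and the resolved libraries carry no replicate number. For genes not resolved into reads, leaving out libraries, regrouping them and estimating a correlation were not run, nor were edgeR with TMM against DESeq2, no count filter and a pseudocount of 0.1 for any gene. Leaving out each library in turn, the log2 ratio of the summed meningeal reads ranged from 2.03 (without library 2 of the positive side) to 3.12 (without library 3), and that of the ventral and striatal reads from -1.62 to -0.97. The 12 resolved called genes kept their sign in all 72 such values, without a test. The count of 25 could not be rerun without the libraries with high meningeal or ventral reads, since genes with a mean above 75 were not resolved into reads. Total depth is unknown. The median standard error was 1.01 among positive calls against 0.24 among negative ones, and low means alone do not set it, since Col1a1 with a mean of 652 has 1.16 in the authors' deposited table.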

Other observations

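Chosen only after their results were seen were the tests of endothelial against meningeal genes, of intermediate progenitors and of pallium-restricted genes with and without shared members, and all readings of reads per library. Interferon-response genes, whose fold changes did not pass the set test, differed between libraries in a way that did not follow the sides. Over 10 resolved genes the summed normalised reads were 450, 654 and 149 on the positive side and 81.8, 486 and 531 on the negative side. Isg15, a ubiquitin-like protein gene induced by interferon, had 66, 104 and 12 reads against 11, 55 and 56, and Ifit3, another interferon-induced gene, had 64, 70 and 3 against 8, 56 and 57. Library 3 of the positive side was the lowest of its side for 10 of the 10 genes.

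Border macrophage genes, a list added after the data were seen, had positive fold changes in 7 of 7 members, with a median log2 of 2.43, and in 5 of 5 with a mean of at least 10, with a median of 2.00. Among them Mrc1, the mannose receptor gene, had 2.87 and Folr2, a folate receptor gene, 2.69 in the authors' deposited table. No gene of the list was called. Over 4 resolved genes the summed normalised reads were 127, 152 and 18.8 on the positive side and 8.09, 33.6 and 17.7 on the negative side, with libraries 1 and 2 of the positive side the highest, as for the meningeal genes.

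The first pattern is the positive fold change of meningeal genes. A lower share of neural cells in general would raise all other cell types alike. The meningeal median exceeded the endothelial median by 3.69 log2 units, which argues against it in these libraries. The permutation across genes (p = 9.8e-04) treated them as independent, while resolved meningeal genes had an estimated correlation of 0.98. That p therefore does not measure the spread between libraries. Unequal amounts of meningeal tissue in the libraries may account for the pattern: 14 of 14 further meningeal genes with a mean of at least 10, none of them in a fixed list, had positive fold changes with a median log2 of 1.80, and over all 17 of that list 16 were positive with a median of 1.53. Meningeal reads stood high in 2 of the 3 positive-side libraries and at the level of the negative side in the other one, and the most abundant called meningeal gene, Col1a1, had a mean of 652 normalised counts in the authors' deposited table. An effect of the Ccnd2 edit, which differs between the same groups, was not tested and stays open.

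For the negative fold change of ventral forebrain genes, migrating interneurons alone would move their own genes at least as far as striatal genes. The striatal median lay below that of the interneuron genes (difference of -2.38 log2 units, permutation p = 3.6e-04). This permutation also treated genes as independent, so its p does not measure the spread between libraries. Of the 10 interneuron genes, 4 are also in the fixed ventral list, and 6 were positive. Unequal amounts of ganglionic eminence or striatal tissue in the libraries could account for the pattern, since 13 of 13 striatal genes had negative fold changes with a median log2 of -2.34. The reads were again uneven within a side, with Dlx6 at 120, 38 and 124 on the negative side, and the abundant ventral gene Sp9 had a mean of 1144 normalised counts in the authors' deposited table. An effect of the edit stays open and untested.

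The last pattern is the small negative shift of cell cycle genes. A larger share of cortical progenitors on that side would take intermediate progenitor genes with it, and these had a median log2 of 0.16 on the opposite side (cameraPR adjusted p = 9.9e-04). This does not exclude it, since the 9 pallium-restricted genes outside that list also lay on the positive side, with a median of 0.095, and the difference of 0.068 between the medians did not pass an exact permutation test (p = 0.71). Unequal amounts of ventral tissue may contribute: 12 of 13 pallium-restricted genes were positive, with a median log2 of 0.28 (exact sign test p = 0.0034), or 8 of 9 without the 4 intermediate progenitor members (exact sign test p = 0.039), but the abundant Neurod6 had 0.01 ± 0.09 and Tbr1 -0.09 ± 0.15 in the authors' deposited table. An effect of the edit on the cell cycle stays open and untested.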
